A study of Mus musculus with 12 samples.

How the data were processed

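The series held 12 PAR-CLIP libraries from female C57BL/6 mouse neural stem cell lines made from embryos at embryonic day 14.5, in 3 groups of 4. PAR-CLIP labels the RNA of living cells with 4-thiouridine, joins it to bound protein with ultraviolet light at 365 nm and sequences the RNA recovered with that protein. Per the labels' protocols, cells received 100 µM 4-thiouridine for 24 hours and 0.15 J/cm2 of light. Cells of the first group carried a GFP tag on both copies of Smchd1, a chromatin protein that takes part in X inactivation. The second group had the same genotype and, per its titles and the series' design text, was not crosslinked, although the treatment protocol of those samples states irradiation. The third group was untagged and crosslinked.

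Per the submitters' processing notes, bcl2fastq and TopHat2 2.1.0 were used with genome build mm10. The values used here came from 1 list of clusters for the whole series. Its values are read counts per cluster as deposited by the authors, with no normalization and no column per sample. The cluster caller, its thresholds, the libraries whose reads were used and the use made of the control libraries are not given in the sources used here. The list held position, strand, sequence and read count of each cluster, with no count of T-to-C changes. For that reason no group was compared with another and no T-to-C share was computed, although both had been planned. Depth per library was likewise not available from these values, and only the sum of reads per cluster is given.

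Positions were read as 1-based and inclusive. They were checked against GENCODE M21 transcripts on GRCm38, the same assembly as mm10: the sequence of 583 of 583 clusters lying inside an annotated exon was equal to the transcript on its strand. Each cluster was assigned at its midpoint to the annotation on its own strand, in the order coding sequence, 3′ UTR, 5′ UTR, non-coding exon and intron, then to antisense if it lay in a gene of the other strand, and otherwise to intergenic sequence. No genome sequence or repeat annotation was used here. Clusters were instead grouped into sequence families, in which clusters were linked when they shared a word of 30 bases on either strand. Copies of repeats form such families, and so do clusters that overlap by 30 or more bases on opposite strands at 1 locus. Reads of 1 sequence could be counted at each of its copies, so the sum over clusters can exceed the number of reads sequenced.

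Shares have Wilson 95% intervals. Intervals and tests cover counting error only, since reads without molecular identifiers are not independent molecules. Because the list has no value per library, no value has a replicate error. The 19 gene lists were tested with a two-sided Fisher exact test of members with a cluster on their strand. The background was annotated protein-coding genes, or all annotated genes for lists with fewer than 5 protein-coding members, a rule set after the list of clusters was first opened and before any list was tested. Under the first background, non-coding members such as Xist, Snhg14 and the mitochondrial ribosomal RNAs were left out of the test. Values were adjusted by Benjamini-Hochberg over the 19 lists. The X chromosome share was measured in 7 ways, each with a two-sided test and adjusted over the 7. Because copies of a family are not independent, intervals for the cluster shares were also taken from 10000 resamplings of whole families. All 256 4-mers were compared with 100 dinucleotide-preserving shuffles of each cluster, with 1 cluster per gene and each distinct sequence outside genes, by 100000 random sign flips, adjusted over the 256. Shuffles had been planned for the case in which no genome was used. Named genes were, by a rule set before the data were examined, the 15 with the most reads and the 10 with the most clusters on their strand, up to 6 members with a cluster of each list (10 for X inactivation, imprinted, protocadherin and Hox lists), Smchd1 and Xist. The values of 1 gene that this rule names are not reported here. The gene lists and the main alternative settings were also set before the data were examined. The sequence families, strand tests, cluster end measures, Y chromosome measures, exonic length test and genes ranked by exonic clusters were added after.

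Both tests were tested on simulated data. In 1500 shuffled sequences with nothing added, 0 of 256 4-mers were called. With 1 4-mer written into 20% of them, that 4-mer was called by the sign-flip permutation test at adjusted p = 0.0128 and had the highest log2 ratio of the 4-mers past the threshold. Of all 256 it ranked 3, behind 2 rare 4-mers far from the threshold, the lower adjusted p of which was 0.36. The first criterion asked for rank 1 of all 256 and was not met. It was replaced, after that outcome was seen, by rank 1 among those past the threshold. Rare 4-mers could thus have a high log2 ratio without passing. In the same simulation 1 further 4-mer was called, which shared 3 adjacent bases with the added one. Of 200 random gene lists of 40 genes, 1.5% were called at p under 0.05, and 100% of lists with 8 added genes were called. Genes with clusters were drawn evenly in the simulated lists, so differences in gene length and clusters shared by several genes were not covered. Shuffling also removed the sequence families, and lists of other sizes or with weaker enrichment were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.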

Results

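The 12 libraries comprised 4 of Smchd1-GFP cells with crosslinking, 4 of Smchd1-GFP cells without crosslinking and 4 of untagged cells with crosslinking. The design asked which RNAs were recovered with tagged Smchd1 above the untagged and uncrosslinked controls. The deposited list had 4762 clusters with 553902 reads summed over clusters. It assigned no read to a library, and the libraries behind it are not given in the sources used here. The tagged group could therefore not be set against either control, and the values below describe the list without a background. A cluster had a median of 14 reads (quartiles 10 to 25, range 2 to 43217) and a median length of 85 bases (range 48 to 823). In a window chosen after the lengths were seen, 4545 clusters (95.4%) were 83 to 86 bases long. With each identical sequence counted once the sum was 307335 reads, and with each sequence family counted once it was 176340.

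The first question was where in the genome the clusters lay. Intergenic sequence held 2342 clusters (49.2%, interval 47.8 to 50.6), and 1194 clusters (25.1%, interval 23.9 to 26.3) lay antisense to a gene. Introns held 957 clusters (20.1%, interval 18.98 to 21.26). All exons together held 269 clusters (5.65%, interval 5.03 to 6.34), of which 128 were in coding sequence, 112 in non-coding exons, 25 in 3′ UTRs and 4 in 5′ UTRs. Non-coding exons held 2.35% of clusters and 7.36% of reads. The exonic share was 14.1% when clusters on either strand of a gene were counted and 3.17% with protein-coding transcripts of the basic set only.

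**Figure D1:**
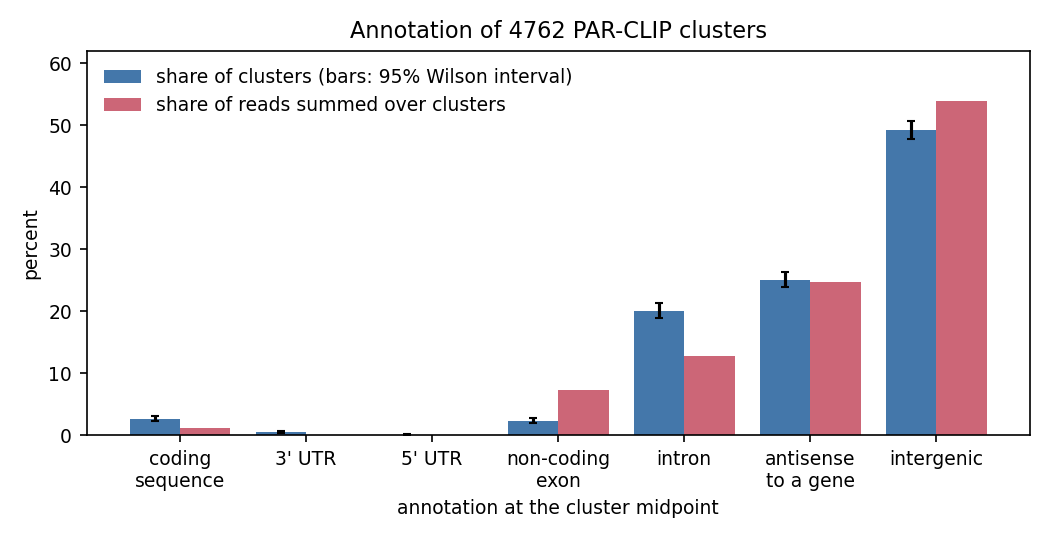
Share of the 4762 clusters (blue, with 95% Wilson intervals) and of the 553902 reads summed over clusters (red), in percent, by annotation at the cluster midpoint on the strand of the cluster. Intergenic sequence held 49.2% of clusters and 53.9% of reads, and coding sequence held 2.69% and 1.22%.

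A few loci held a large part of the reads. The cluster with the most reads, 43217 or 7.80% of the sum, lay on chromosome 5 from 146261110 to 146261204 on the minus strand, antisense in Cdk8, which encodes a kinase of the Mediator complex, and shared no 30-base word with another cluster. The second, with 25832 reads (4.66%), lay on chromosome 17 from 39846588 to 39847410 on the minus strand, in the non-coding exon of CT010467.1, annotated as ribosomal RNA. The third, with 7837 reads, lay on chromosome 13 from 44869917 to 44870018 on the minus strand, antisense in Jarid2, which encodes a partner of Polycomb complex PRC2, and belonged to a family of 16 clusters. The clusters in Cdk8 and Jarid2 lay outside exons and opposite to the gene, so they are not reads of these mRNAs. What these 2 sequences are was not tested. The next 5 clusters, with 5951 to 5965 reads each, were members of 1 family of 15 clusters spread over several chromosomes. That family held overlapping clusters of opposite strands at 1 locus on chromosome 8, so it had fewer loci than clusters. The 10 clusters with the most reads held 21.3% of the sum.

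Repeated sequence was common. The list had 3560 distinct sequences, and 1464 clusters (30.7%) had a sequence that was listed at more than 1 locus, the most frequent at 76 loci. Sequence families of 2 or more held 1862 clusters (39.1%), and the 2900 clusters alone in their family held 17.7% of the reads. Overlapping clusters on opposite strands at 1 locus also form a family, so 39.1% is not a share of repeat copies alone. The largest family had 268 clusters on 21 chromosomes with 74447 reads, and 68.3% of them were intergenic. The second largest had 221 clusters on 21 chromosomes with 118117 reads, 21.3% of the sum.

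Each of the 15 genes with the most reads on their strand had at least 1 cluster in a shared family. CT010467.1 on chromosome 17 (39846353 to 39848827) had 31733 reads in 5 clusters, and the overlapping long non-coding RNAs AY036118 and Gm42418 had 5708 and 3877 reads. Filip1l and Cmss1, which overlap on opposite strands of chromosome 16, had 6743 and 6310 reads, all intronic, with 4 of their 5 clusters in shared families. Single intronic clusters gave the 2352 reads of the phosphatase gene Inpp4b, the 1982 of the importin gene Kpna1, the 1842 of Lingo2 and the 1833 of Gap43, a growth cone protein, each in a shared family. Further genes of this group were D130009I18Rik (4414 reads), Phkb (3149), AC142213.1 (2422) and Gpr158 (1830). By number of clusters, Snhg14, the long host RNA of the Snrpn to Ube3a imprinted domain on chromosome 7, led with 14 clusters on its strand and 112 reads. All 18 of its clusters on both strands were intronic and in shared families. Macrod2 had 6 clusters with 118 reads, Gm28437, a pseudogene on chromosome 1, had 4 with 245, and Gm26573 had 4 with 80.

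The X chromosome was examined because Smchd1 acts on the inactive X and the cells were female. Of the 1037 genes with a cluster on chromosomes 1 to 19 and X, 52 were X-linked (5.01%, interval 3.84 to 6.52), against 4.85% of annotated genes, a difference that did not pass the two-sided Fisher exact test (odds ratio 1.04, p = 0.771, adjusted p = 0.771). Counted by clusters, 360 of 4579 (7.86%, interval 7.12 to 8.68) were on X, against 4.85% of genes (two-sided Fisher exact test, adjusted p = 3.3e-16). That test and interval treat copies of 1 family as independent. In measures added after the data were seen, whole sequence families were resampled 10000 times. The interval for all clusters was then 6.32 to 9.35, which includes the X share of chromosome span, 6.49%. The 1717 clusters in 192 shared families had 12.1% on X (interval 8.82 to 15.4), above the span share, and the 2862 alone in their family had 5.31% (interval 4.51 to 6.15), below it. The difference was 6.80 percentage points (interval 3.41 to 10.2). Reads of 1 sequence could be counted at each of its copies, and no repeat annotation was used. The share of shared families therefore cannot tell RNA recovered from X apart from repeat copies that lie there. Shared families also include overlapping clusters of opposite strands at 1 locus.

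**Figure D2:**
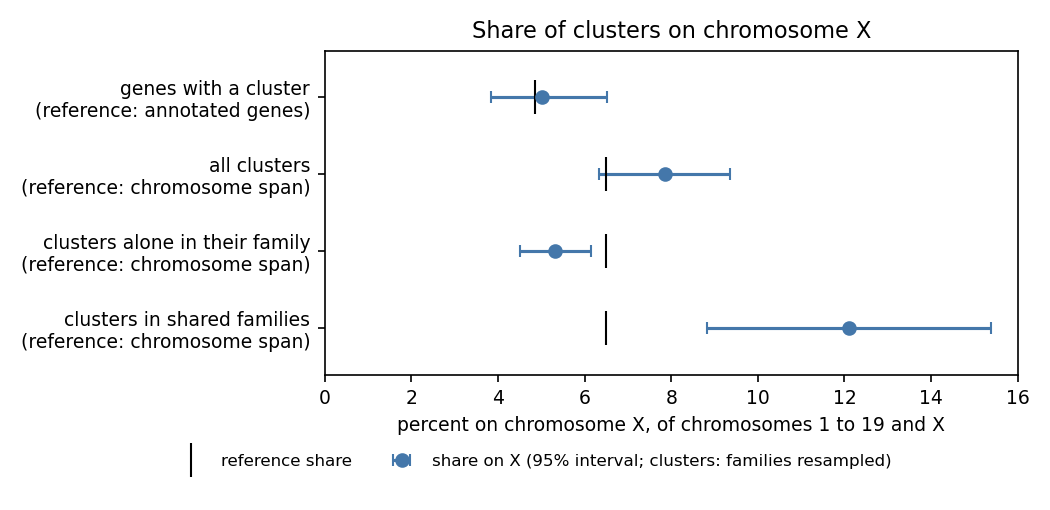
Percent on chromosome X, of chromosomes 1 to 19 and X, for genes with a cluster (point, 95% Wilson interval) and for clusters (points, 95% intervals from resampled sequence families), with the reference share as a black tick. Genes with a cluster were at 5.01% against 4.85%, clusters alone in their family at 5.31% and clusters in shared families at 12.1% against a span share of 6.49%.

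Xist, the RNA that coats the inactive X (chromosome X, 103460366 to 103483254), its antisense partner Tsix and Smchd1 itself (chromosome 17, 71344489 to 71475343) had 0 clusters on either strand. The list starts at 2 reads and its calling threshold is not given in the sources used here, so reads below that threshold could not be seen. Of the 5 protein-coding members of the X inactivation list, 0 had a cluster. Of 32 protein-coding imprinted genes, 1 had a cluster on its strand, Trappc9 with 61 reads in 3 clusters (odds ratio 0.84, Fisher exact test, adjusted p = 1). With genes of any biotype, 2 of 41 imprinted genes had a cluster, the other being Snhg14 (odds ratio 2.64, Fisher exact test, adjusted p = 0.437). The 56 clustered protocadherins, cell surface proteins of neurons whose expression Smchd1 is known to affect, and the 39 Hox genes had 0 members with a cluster on their strand (Fisher exact test, adjusted p = 0.743 and 0.748). Few were expected: draws matched on exonic length held a mean of 2.06 protocadherins, 0.76 Hox genes and 0.33 X inactivation genes. Draws matched on gene span held 4.87 protocadherins (permutation test, adjusted p = 0.0608) and 0.37 Hox genes. A count of 0 in these lists therefore does not show a lack of clusters.

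Of the 19 lists, 1 passed: 11 of 13 mitochondrially encoded protein-coding genes had a cluster on their strand, against 3.71% of protein-coding genes (odds ratio 145, two-sided Fisher exact test, adjusted p = 2.4e-13). The members without one were mt-Co2 and mt-Atp8. The test takes the 13 genes as independent members, although they all lie close together on the mitochondrial genome. The mitochondrial 12S ribosomal RNA mt-Rnr1 had 2063 reads in 2 clusters and the 16S ribosomal RNA mt-Rnr2 had 425 in 3, and with both strands counted they had 4510 and 2260. Among subunits of the respiratory chain, mt-Nd5 had 729 reads in 6 clusters, mt-Nd2 586 in 2, mt-Cytb 457 in 4, mt-Nd4 254 in 5 and mt-Co1 239 in 4. The mitochondrial genome had 67 clusters with 12482 reads, and 37 of these clusters were in shared families. Some of the 37 were linked because they overlapped on opposite strands, as at 73 to 198 and 158 to 593 in mt-Rnr1. With clusters alone in their family, 6 of the 13 protein-coding genes had a cluster (odds ratio 28.7, Fisher exact test, adjusted p = 1.7e-05). This setting also left out overlapping clusters of opposite strands, so it is not a control for repeated sequence alone.

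**Figure D3:**
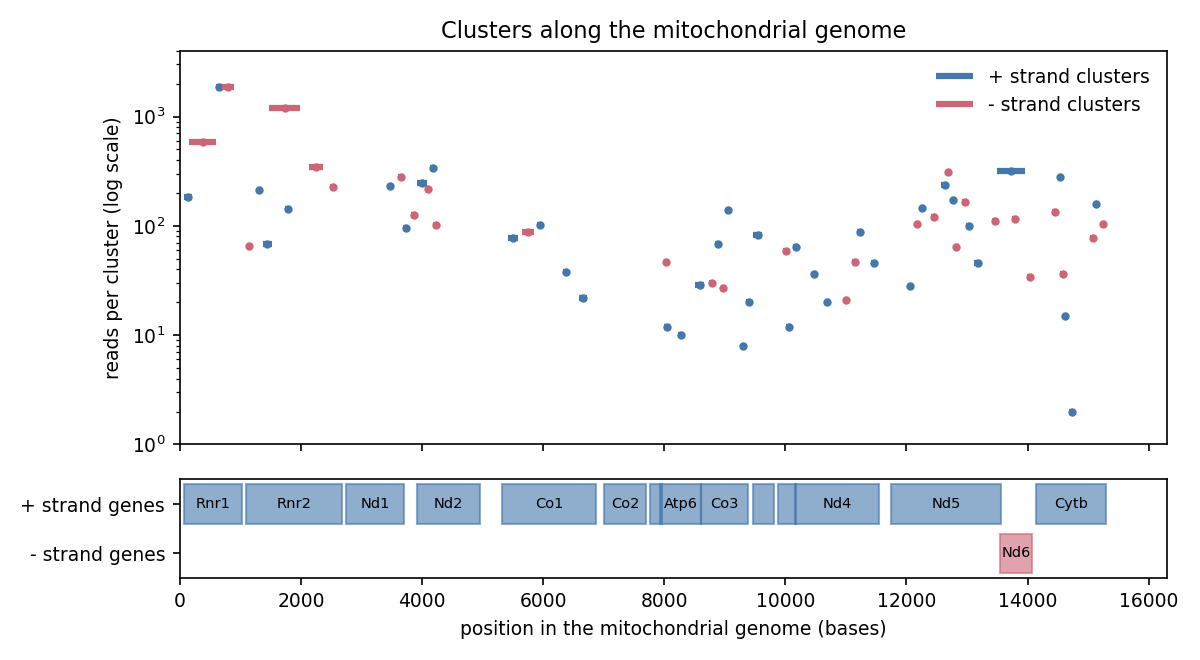
Reads per cluster (log scale) of the 67 mitochondrial clusters along the mitochondrial genome (position in bases), blue on the plus strand and red on the minus strand, with ribosomal RNA and protein-coding genes below. Clusters lay on both strands of the genes, 39 on the strand of their gene and 28 on the other.

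Small structured RNAs had 3 of 25 members with a cluster (odds ratio 7.03, Fisher exact test, adjusted p = 0.111): the signal recognition particle RNAs Rn7s1 and Rn7s2 with 62 and 60 reads and the U1 RNA Rnu1a1 with 23. The list passed the Fisher exact test with clusters at or above the median reads (adjusted p = 0.021) and with exons only (adjusted p = 0.00136). It also passed a permutation test of 10000 draws matched on exonic length (adjusted p = 0.0038) or gene span (adjusted p = 0.0019). It had 0 members among clusters alone in their family. Rn7s1 and Rn7s2 also had 107 reads each on the opposite strand, and all their clusters were in shared families. The same reads may therefore be counted in both, while each test took them as independent members. Nuclear long non-coding RNAs had 2 of 19 (odds ratio 6.06, exact adjusted p = 0.318): Malat1, a nuclear speckle RNA, with 484 reads in 3 clusters, and Sox2ot with 19. Chromatin partners had 3 of 27 (odds ratio 3.25, exact adjusted p = 0.366): Jarid2 with 108 reads, the cohesin subunit Smc1a with 108, and Spen, an Xist-binding repressor, with 23. Neural stem cell markers had 2 of 19 (odds ratio 3.06, exact adjusted p = 0.535), the RNA-binding protein Msi2 with 26 reads and the glutamate transporter Slc1a3 with 15. Cytoskeleton and housekeeping genes had 2 of 20 (odds ratio 2.89, exact adjusted p = 0.535), Actb with 32 reads and nucleolin, Ncl, with 10. Counted in exons on either strand, an alternative added after the data were seen, that list had 5 of 20 (odds ratio 20.7, exact adjusted p = 8.3e-05). Cytoplasmic ribosomal proteins had 1 of 79 (odds ratio 0.33, exact adjusted p = 0.748), Rps19 with 12 reads, and translation factors had 1 of 20 (adjusted p = 0.841), Eef1a1 with 23. In exons on either strand translation factors had 4 of 20 (odds ratio 15.5, exact adjusted p = 0.00122). Neuron markers had Gap43 alone of 15 (exact adjusted p = 0.748), and fibroblast and endothelial markers had Col3a1 alone of 10, with 33 reads in 2 clusters (adjusted p = 0.748). The 34 RNA-binding proteins (exact adjusted p = 0.932), 18 replication-dependent histones, 10 astrocyte, 10 oligodendrocyte and 10 microglia and blood markers (each adjusted p = 1) had 0. Expression was not measured here.

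Sequence was examined in 3438 clusters for words shared beyond base composition. Cluster bases were 31.3% T, 27.0% A, 21.6% C and 20.1% G. Of 256 4-mers, 151 passed, 71 of them more frequent and 80 less frequent than in dinucleotide-preserving shuffles. The highest was CGTG, found 281 times against 198 in shuffles (log2 ratio 0.50, sign-flip permutation test, adjusted p = 3.2e-05), followed by CCCG (0.37), TTCC (0.37), TCCA (0.37) and CCAG (0.36). None of these 5 passed in exonic clusters (CGTG adjusted p = 0.426 and CCCG adjusted p = 0.0527 by the permutation test) or against sequence 100 bases away in the same transcripts, where CGTG (log2 ratio -0.07), TCCA (-0.07) and CCAG (-0.08) were below 0. The lowest was GTAC, found 24 times against 564 (log2 ratio -4.50, same permutation test, adjusted p = 3.2e-05, the smallest the 100000 sign flips gave). In exonic clusters 12 4-mers passed, 1 higher and 11 lower, and against the transcript sequence 8 passed, 6 higher and 2 lower, with GTAC lower in both. Shuffles do not separate the composition of the genome from that of bound RNA.

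Cluster starts shared a sequence. Of all clusters 3758 (78.9%, interval 77.7 to 80.1) began with AC, against 4.48% AC among adjacent bases within clusters. Of 453 exonic clusters that began with AC and had known upstream sequence, 336 (74.2%, interval 70.0 to 78.0) had GT just before the start, against 5.61% at 100 bases upstream.

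**Figure D4:**
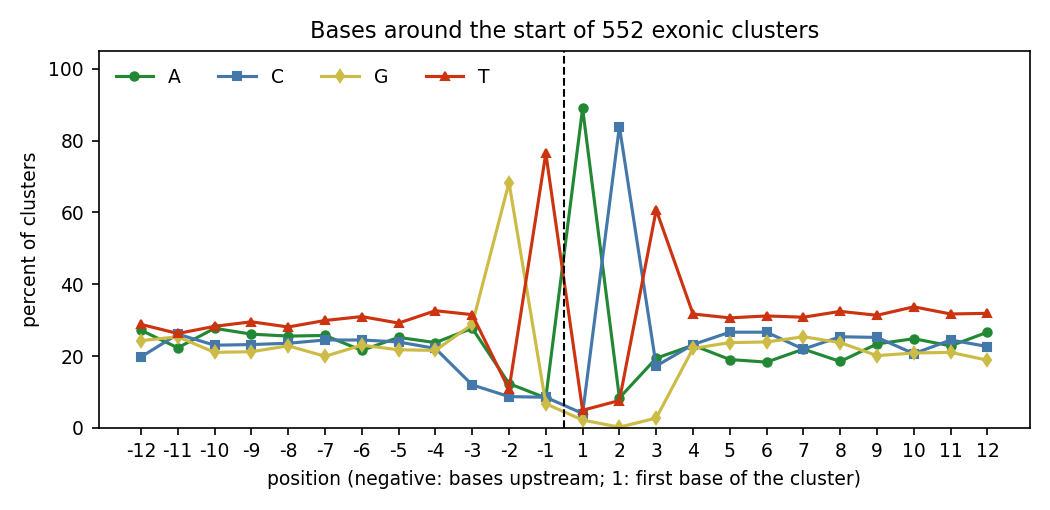
Percent of 552 exonic clusters with each base (A, C, G, T) by position, with the dashed line at the start of the cluster. G and T were at 68.3% and 76.4% in the last bases before the start, and A was at 88.9% in the first base of the cluster.

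Clusters in exons were compared by strand. In exons of nuclear protein-coding genes 142 clusters lay on the strand of the gene and 276 (66.0%, interval 61.4 to 70.4) on the opposite strand, which differed from equal shares (two-sided exact binomial test, adjusted over 5 groups of clusters p = 2.7e-10). In mitochondrial genes 28 of 67 lay opposite (41.8%, interval 30.7 to 53.7, adjusted p = 0.277), and the odds ratio between nuclear and mitochondrial clusters was 2.71 (two-sided Fisher exact p = 0.00021). That Fisher test takes clusters as independent, although some of the mitochondrial ones overlap. Introns had 820 of 1679 on the opposite strand (48.8%, exact binomial test, adjusted p = 0.354), snRNA and other small RNA genes 25 of 38 (adjusted p = 0.182) and long intergenic non-coding RNA genes 13 of 19 (adjusted p = 0.277). By reads, 66.6% lay on the opposite strand in nuclear protein-coding exons, 86.9% in snRNA and other small RNA genes and 78.8% in long intergenic non-coding RNA genes. Mitochondrial genes had 55.0% of reads and introns 68.3% on the opposite strand, so the direction turned in these 2. The intron share of reads was 57.1% without the cluster antisense in Cdk8 and 48.6% without the 10 clusters of the intron group with the most reads. Both alternatives were added after the data were seen.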

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

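The tests of explanations in this part were chosen only after the result was seen, with their bounds.

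Signal appeared on a chromosome that female cells lack and that the X chromosome comparison left out: 83 clusters with 26389 reads lay on the Y chromosome. Of these, 78 (94.0%, interval 86.7 to 97.4) belonged to a family with a cluster on another chromosome, which is consistent with reads of repeats being placed on Y copies, and 5 clusters with 205 reads did not. Y clusters in exons numbered 0. Mostly male cells cannot be told apart from this by single-copy genes, since exons of the 5 Y genes Ddx3y, Eif2s3y, Kdm5d, Uty and Usp9y and of their X partners held 0 clusters together. No biological explanation was tested.

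Unplaced or unlocalized scaffolds held 33 clusters with 826 reads, which the X chromosome comparison also left out.

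Most clusters began with AC, and most exonic ones of these with known upstream sequence had GT before it. Cutting by RNase T1, an enzyme of the usual PAR-CLIP procedure, follows G, and 6.70% (interval 4.90 to 9.10) of 552 exonic clusters had G just upstream, which argues against it as the source of the starts. A binding or crosslinking preference for GTAC would place it within clusters, and the ratio of GTAC in 448 exonic clusters to their flanks was 0.028 (3 against a mean of 108 per flank, exact binomial p = 1.3e-33). A cut at GTAC would remove it from within clusters whatever the preference, so this ratio cannot decide on a preference. Cutting of double-stranded DNA or cDNA at GTAC, the site of the restriction enzyme RsaI, stays open as a hypothesis. GT stood upstream in 74.2% of the 453 exonic clusters that began with AC, a narrower set than the 552 above. In addition, 38 pairs of clusters abutted on opposite strands, against at most 1 pair at any other offset within 20 bases. Such a cut would not give the 702 clusters (14.7%) that began with AA, of which 92.3% were in shared families. No label used here records such a cut, and whether the list holds RNA trimmed in the usual way stays open, with 95.4% of clusters 83 to 86 bases long.

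Exons of nuclear protein-coding genes had more clusters on the opposite strand than on their own. A strand recorded as its opposite throughout would put at least 90% there. A strand not kept at all would give equal shares, for which a range of 40% to 60% was allowed. The measured 66.0% (interval 61.7 to 70.3 with whole genes resampled) lay below the first range, which argues only against a strand reversed in every cluster. A strand reversed in part of the clusters could also give an intermediate share, so this bound cannot decide on it. Every resampled interval lay above equal shares, so equal shares do not describe these exons. By the allowed range the second was not decided: the interval lay above 60% for all clusters but reached 59.6% for those starting with AC. Introns were at 48.8% by clusters and 68.3% by reads, the latter 57.1% without the 1 cluster with the most reads. For the list as a whole the values therefore do not decide. A strand kept or reversed for part of the list only and antisense RNA were not tested and stay open.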

How the results depend on the processing

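All alternatives that restricted clusters to those alone in their family, used chromosome span or gene span, counted either strand for lists or named genes, removed first bases, took 1 cluster per family or used transcript flanks, and all those of the strand share, were chosen after seeing the data. No paired analysis was possible because the list has no value per sample. For the same reason the alternatives of both group comparisons, of the T-to-C share and of conversion locations per cluster were not run.

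The exonic share of 5.65% moved to 14.1% on either strand, 6.81% at or above the median reads and 3.17% with basic protein-coding transcripts. The intronic share of 20.1% moved to 36.7% on either strand, 16.8% with basic protein-coding transcripts and 22.6% alone in family. The intergenic share of 49.2% moved to 58.3% and 41.6% in the last 2 settings. The X odds ratio of 1.04 passed at 1.67 by clusters, 1.23 by clusters against span and 1.98 in shared families, in tests that take copies of a family as independent, and reversed to 0.81 alone in family. With families resampled, the interval of all clusters included the span share. Lists past the threshold rose from 1 to 2 at or above the median reads, 2 in exons, 2 with matched exonic length, 2 with matched gene span, 4 on either strand and 4 in exons on either strand. Small structured RNAs were the second list in each of these, on either strand joined by cytoskeleton and housekeeping genes (exact adjusted p = 0.0482) and protocadherins (14 of 56, exact adjusted p = 0.00019), and in exons on either strand by cytoskeleton and housekeeping genes and translation factors. The 14 protocadherins came from 1 cluster with 25 reads inside overlapping genes, and in exons on either strand 1 of 56 remained (exact adjusted p = 1). The mitochondrial list passed in all 8 alternatives (adjusted p 1.7e-21 to 0.0038), with its odds ratio down from 145 to 28.7 alone in family. Called 4-mers fell from 151 to 12 in exonic clusters and 8 against transcript flanks, with fewer sequences tested. Apart from these constructions, the cause was not tested.

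GTAC stayed depleted in all 5 alternatives (log2 ratio -4.77 to -2.24), and the opposite-strand share stayed above 50% in all 3 (64.3% to 69.5%). Of 41 named genes, 24 had reads on both strands above the Wilson interval of the reads on their strand. The count on both strands contains the other and can only rise or stay equal, so this is a description and no test. Depth per library limits every value and is unknown.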

Other observations

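The genes and the test in this part were chosen after the data were seen. Ranked by exonic clusters on either strand, nuclear protein-coding genes were led by the proliferation marker Mki67, with 12 clusters and 1034 reads, 9 of the clusters on the opposite strand. Apc, a regulator of Wnt signalling, followed with 11 clusters and 643 reads, and Ptprz1, a receptor phosphatase of neural progenitors, with 9 and 806. Prrc2c had 7 clusters with 603 reads, Ankrd11 5 with 435 and Scd2 5 with 129. The cohesin subunit Smc1a and the chaperone Hsp90b1 had 4 each, with 219 and 256 reads. Of 342 nuclear protein-coding genes with an exonic cluster, 34 had 2 or more, and 26 of these 34 had one on both strands.

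The 342 genes with an exonic cluster may be in the list because longer exonic sequence offers more positions for a cluster. The test below sets all of them against the rest and does not address the ranking above. Genes with an exonic cluster had a median exonic length of 7484 bases and the 21673 without one had 3457, a log2 difference of 1.11 (permutation test with 10000 permutations, p = 0.0001, the smallest they can give). Expression was not measured, so a higher abundance of these RNAs stays open beside it.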
